A study of Caenorhabditis elegans with 4 samples.

How the data were processed

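RNA polymerase II was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in early embryos of *Caenorhabditis elegans* strain N2, the wild-type laboratory strain, grown at 20 degrees Celsius. Per the labels, 2 ChIP libraries were made with 8WG16, a mouse monoclonal antibody against the heptapeptide repeat at the C-terminal end of the largest polymerase II subunit, and 2 input libraries were made from DNA without immunoprecipitation. Each ChIP library has the replicate number and extraction of 1 input library. The general protocol text in the labels describes a precipitation with anti-GFP serum, whereas the antibody field of the ChIP libraries names 8WG16, and the latter was followed here.

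The data were 1 combined list of enriched regions for all 4 libraries. Per the file headers the coordinates are those of WormBase release WS180, and the source field of each line names PeakSeq, a caller that tests ChIP against input reads region by region. The deposited value of each region is a q-value, a p-value corrected for multiple tests, and the largest listed was just under 0.01. The version and settings of PeakSeq, the read mapper, the depth of each library and the way in which the replicates were combined are not given in the sources used here. The list has no column for a single library, so no value has a replicate error and no difference between replicates was measured. Other numbers in the deposited file are the first and last base of each region, printed here 1-based as in the file.

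The gene table at hand belongs to assembly WBcel235 and not to WS180, and no coordinates were moved between builds. Regions were therefore not assigned to genes. The planned tests of gene starts, positions within genes, strength by position in the gene and the 17 gene lists were not run, and no gene is named. Regions were named by a rule fixed before the data were examined, as the 25 strongest by q-value and the 5 widest. The planned gene-based test of the X chromosome was replaced, after the data were seen, by a test on region number per 1 Mb bin.

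Chromosome length was taken as the span from the first to the last base of the listed regions. Region number, covered length, width and −log10 of the deposited q-value were summarised per chromosome. The X chromosome was compared with the autosomes over complete 1 Mb bins, and over single regions for log2 width, with two-sided permutation tests of 100000 label permutations. Neither bins nor regions are independent replicates. The central 33.3% of each chromosome span was compared with its outer parts by an exact two-sided sign-flip permutation test over the 6 chromosomes, whose smallest possible p is 0.031. The distance between neighbours was compared with 1000 random placements that kept the region widths, the spans and the smallest gap of 200 bp. 8 tests formed 1 family and were adjusted by the Benjamini-Hochberg method. Of these, 5 were chosen after the data were seen (the 4 of the X chromosome against the autosomes and that of spacing), which the adjustment does not allow for.

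Read numbers were recovered from the deposited q-values, a step added after the data were seen. Where neighbouring lines had equal p, the q-value fell by the ratio of their ranks, which gave the rank of each line. This held at 2665 pairs of neighbours and placed the first listed region at rank 48, so that 47 stronger ranks were not analysed here. The product of q and rank was then compared with exact upper tails of a binomial distribution with probability 0.5. A total of 18572 tested regions turned 68.3% of 41 scanned values into exact tails, and the next best total gave 0.0%. With that total, 8116 of the 8121 regions (99.9%) matched exactly 1 pair of ChIP and input read numbers, to within 1e-09 in the natural logarithm of p. With a total lower or higher by 1, 0.0% did. The input number is the one that entered the authors' test, after any scaling they applied. A fold is the ratio of ChIP to input reads of a region, with a 95% Clopper-Pearson interval. The interval treats both numbers as raw counts, so it is not exact if the input was scaled. At most it covers counting error, since reads without molecular identifiers are not independent molecules. In a simulated list of 7134 regions with 30 ranks removed, the same steps returned the removed ranks, the number of tested regions and 100.0% of the read pairs. In simulated bins the permutation test called 3.0% of 100 sets without a difference and 100.0% of 100 sets in which the X level was halved. Apart from the halved X level, these bins were drawn independently around a common mean. The real autosomes differed in mean and neighbouring bins are not independent, so these shares do not carry over to the real bins.

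Alternatives were the stronger 50% of the regions, other bin sizes, definitions of the middle and distances, covered length in place of region number, merging of neighbours, matching on width or reads, and leaving out each autosome. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.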

Results

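The series asked where RNA polymerase II is bound in the genome of early *C. elegans* embryos. Polymerase II is the enzyme that transcribes protein-coding genes, and AMA-1 is its largest subunit. The 2 ChIP and 2 input libraries were represented by 1 combined list of 8121 enriched regions on the 5 autosomes and the X chromosome. The regions covered 7.26 Mb, or 7.28% of the span between the first and last region of each chromosome. Their widths ran from 1 to 13431 bp, with a median of 506 bp and quartiles of 223 and 1035 bp. The q-values ran from 1.55e-300 to 0.01. The depth of each library is unknown. The recovered read numbers placed 1726661 ChIP reads and 713210 input reads in 8116 regions, with a median of 162 reads of both kinds per region and a range of 19 to 4993. Input reads here and below are numbers after any scaling by the authors. All values below come from the combined list and have no replicate error. All tests of the X chromosome against the autosomes, the test of spacing and the comparison on the 5 autosomes alone were chosen after the data were seen.

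Polymerase II regions were sparse on the X chromosome and dense on chromosomes I and III. Chromosome I carried 1923 regions, or 128.5 per Mb, and chromosome III carried 1618, or 118.0 per Mb. Chromosome II followed with 95.5 per Mb, chromosome IV with 75.7 and chromosome V with 64.7. The X chromosome carried 461 regions, or 26.2 per Mb, so that it made up 17.7% of the span and 5.68% of the regions. The autosomes together had 93.3 regions per Mb, 3.56 times the X level. The covered length differed less, with 78.6 kb per Mb on the autosomes and 45.3 kb per Mb on the X chromosome, a ratio of 1.73.

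Over complete 1 Mb bins, the X chromosome had 26.2 ± 7.67 regions per bin (SD over 17 bins) and the autosomes had 92.0 ± 32.7 (SD over 79 bins). The difference, X minus autosomes, was −65.8 regions per bin and exceeded the spread between bins (permutation test, p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 1.6e-05). The X bins held between 10 and 37 regions, and 5 of the 79 autosomal bins held 37 or fewer. The lowest autosomal bin, with 27 regions, lay on chromosome V from 15 to 16 Mb. The highest bin, with 165 regions, lay on chromosome I from 2 to 3 Mb. Neighbouring bins are not independent. With 1 X chromosome against 5 autosomes, an exact permutation over whole chromosomes cannot give a p below 0.167, and the X chromosome was the lowest of the 6.

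**Figure D1:**
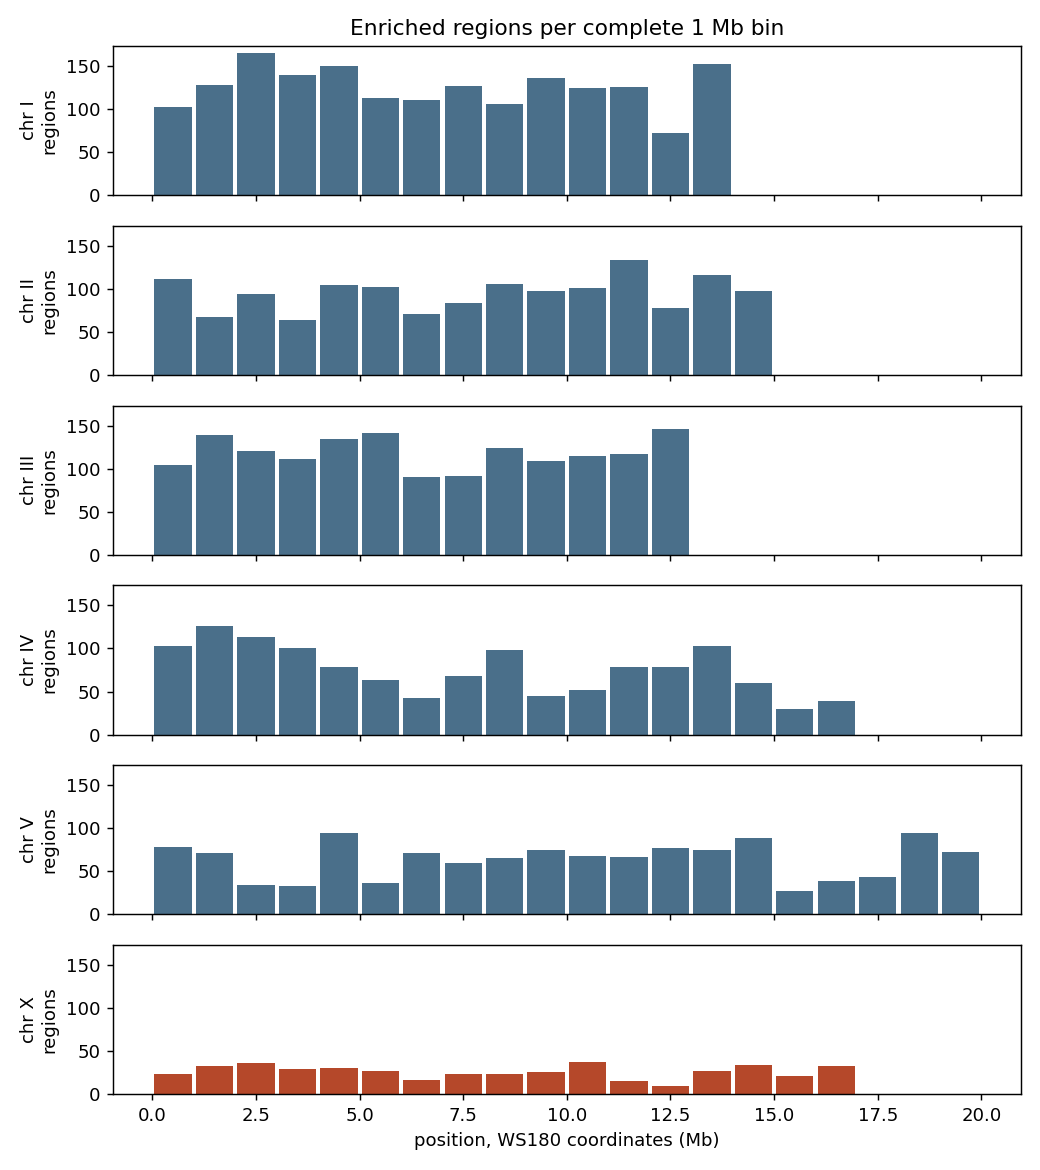
Number of enriched regions (vertical axis, regions per bin) in each complete 1 Mb bin along the 6 chromosomes (horizontal axis, WS180 position in Mb), with autosomes in blue and the X chromosome in red. The X bins lie between 10 and 37 regions, and the highest autosomal bin, on chromosome I, holds 165.

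The regions of the X chromosome were wider than those of the autosomes and had a lower fold of ChIP over input reads. The median width was 1028 bp on the X chromosome and 487 bp on the autosomes, where single chromosomes ranged from 416 bp on chromosome I to 615 bp on chromosome V. The mean difference was 1.28 on the log2 scale (permutation test over regions, p = 1e-05, the smallest possible, adjusted p = 1.6e-05). The difference in width was 0.84 when neighbours within 1000 bp were merged. Only regions that passed the q-value limit are listed, and at a lower fold a region needs more reads to pass. The limit can thus remove narrow X regions, and width was not compared at matched fold. Regions over 5 kb made up 6.72% of the X regions and 1.54% of the autosomal regions. Regions under 20 bp made up 0.868% on the X chromosome and 3.36% on the autosomes. The median fold was 1.82 on the X chromosome (quartiles 1.56 and 2.19) and 2.43 on the autosomes (quartiles 1.97 and 3.14). Among the autosomes the median fold was lowest on chromosome IV, at 2.30, and highest on chromosome I, at 2.52. The mean log2 fold was lower by 0.44 on the X chromosome than on the autosomes (X minus autosomes −0.44, 95% bootstrap interval −0.48 to −0.41, permutation test over regions, p = 1e-05, adjusted p = 1.6e-05). At matched width, X regions held more input reads than autosomal regions, by 0.27 on the log2 scale (95% bootstrap interval 0.23 to 0.31), and fewer ChIP reads (−0.13, −0.18 to −0.09). The mean −log10 q was 1.66 higher on the X chromosome, which did not pass the test (permutation p = 0.186, adjusted p = 0.188). The median −log10 q was 4.65 on the X chromosome and 5.17 on the autosomes, so that mean and median differed in direction.

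**Figure D2:**
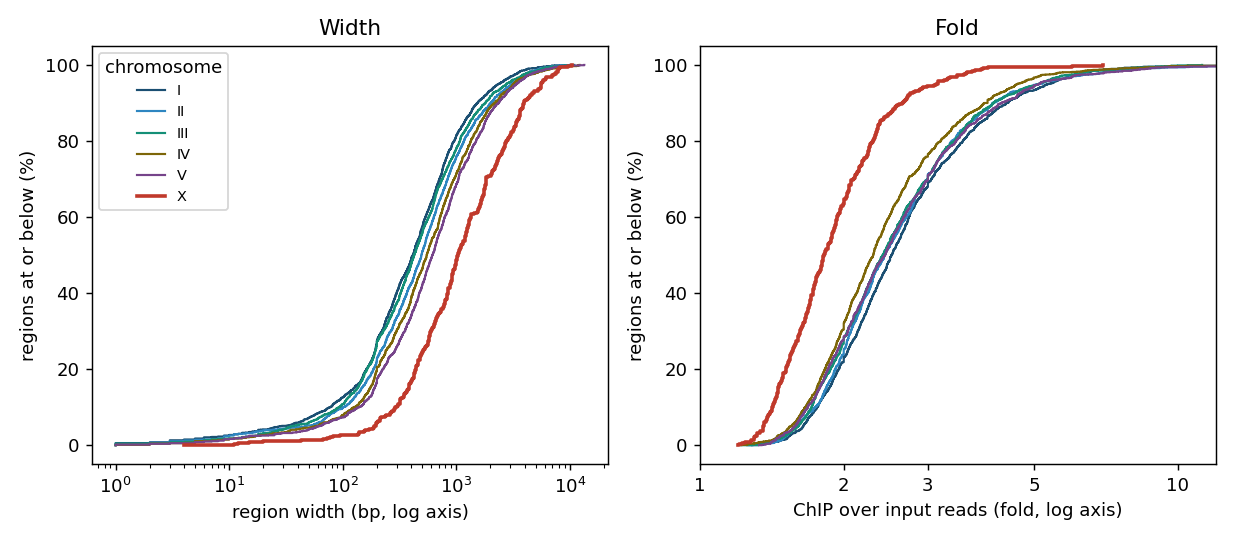
Cumulative share of regions (vertical axes, %) by region width in bp (left, log axis) and by the fold of ChIP over input reads (right, log axis shown up to 12), with 1 line per chromosome and the X chromosome in red. The X line lies to the right for width, with a median of 1028 bp, and to the left for fold, with a median of 1.82.

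The strongest listed regions were several kb wide. The 47 ranks above them were not analysed here. The first by q-value lay on chromosome II from 10059944 to 10066962 (7019 bp, q = 1.55e-300), followed by chromosome IV from 1908077 to 1919803 (11727 bp, q = 1.90e-298) and chromosome IV from 11405480 to 11407880 (2401 bp, q = 3.71e-296). These 3 had no recoverable read numbers. The region on chromosome IV from 17276929 to 17282131 held 2529 ChIP and 576 input reads, a fold of 4.39 (95% interval 4.01 to 4.81). The region on chromosome I from 2821359 to 2827683 held 2165 ChIP and 413 input reads, a fold of 5.24 (4.72 to 5.84). Of the 25 strongest listed regions, 6 lay on chromosome I, 3 on II, 4 on III, 5 on IV, 4 on V and 3 on the X chromosome. Their median width was 6.90 kb, and the median fold of the 22 with read numbers was 4.04, with a range of 2.93 to 8.44. Only 4 of the 25 were narrower than 3 kb. The highest fold among these 22 was that of chromosome I from 4171988 to 4173606, with 1427 ChIP and 169 input reads (8.44, 7.19 to 9.96). On the X chromosome the region from 14489871 to 14491661 held 1401 ChIP and 201 input reads, a fold of 6.97 (6.01 to 8.12). The strongest X region, from 5478760 to 5485752, held 2980 ChIP and 826 input reads, a fold of 3.61 (3.34 to 3.90).

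The 5 widest listed regions lay on chromosomes IV and V. The widest of them, on chromosome V from 13164950 to 13178380, spanned 13.4 kb at a fold of 3.09 (2.88 to 3.31). Chromosome IV from 10667964 to 10680190 spanned 12.2 kb at a fold of 1.99 (1.87 to 2.11). Chromosome V from 4498921 to 4511110 also spanned 12.2 kb, at a fold of 3.15 (2.94 to 3.38). Chromosome IV from 7132739 to 7144608 spanned 11.9 kb at a fold of 2.35 (2.21 to 2.50), and the fifth was the region on chromosome IV from 1908077 to 1919803, at 11.7 kb. Across the 8121 regions, wider regions had lower q-values (Spearman rho = 0.70 and Pearson r = 0.47 between log10 width and −log10 q, permutation p = 1e-05 for each, adjusted p = 1.6e-05). A wider region holds more reads, and regions are not independent replicates.

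**Figure D3:**
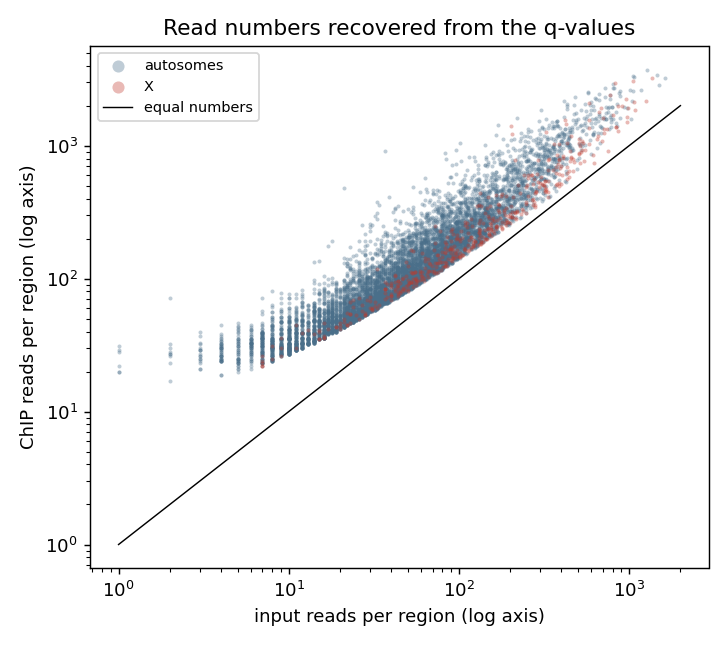
ChIP reads (vertical axis, log) against input reads (horizontal axis, log) recovered for each of 8116 regions, with autosomal regions in blue, X regions in red and a black line where both numbers are equal. All points lie above the line, and the X regions lie near the lower edge of the cloud, at a median fold of 1.82 against 2.43 for the autosomes.

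Neighbouring regions lay closer together than in uniform random placements. Of the 8115 distances between neighbours on a chromosome, 42.0% were under 1000 bp, against 8.11% on average in random placements, where the highest share was 9.09% (random-placement permutation test, p = 0.000999, the smallest that 1000 placements can give, adjusted p = 0.00133). No 2 regions were closer than 200 bp. The placements were uniform over each span, so any uneven spread of regions along a chromosome departs from them. Whether close neighbours are separate sites or pieces of 1 enriched stretch was not tested. The densest 100 kb window of the autosomes was on chromosome I from 14500001 to 14600000, with 38 regions, and the densest of the X chromosome was from 13800001 to 13900000, with 10. At the other end, chromosome V had no region between 2708208 and 3190782, a stretch of 483 kb, and the X chromosome had none between 11606510 and 12075742, a stretch of 469 kb. Of the 100 kb windows, 18.2% were empty on the X chromosome, 15.9% on chromosome V, 7.47% on chromosome IV and 0.671% on chromosome I.

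Chromosome middles and ends differed in the width of the regions more than in their number. The central 33.3% of the chromosome spans had 80.5 ± 34.9 regions per Mb and the outer parts 86.9 ± 39.2 (SD over 6 chromosomes). The number was lower in the middle on 5 of 6 chromosomes, the exception being chromosome V with 69.5 per Mb in the middle and 62.3 outside, and the difference did not pass the test (exact sign-flip permutation test, p = 0.188, adjusted p = 0.188). The direction turned when covered length was counted, with 81.9 ± 20.3 kb per Mb in the central parts and 70.4 ± 16 kb per Mb in the outer parts, higher in the middle on 6 of 6 chromosomes (exact sign-flip permutation p = 0.031, unadjusted and the smallest possible). The X chromosome contributed least to this, with 45.5 kb per Mb in the middle and 45.3 outside, yet the test passes only with it. With the 5 autosomes alone p was 0.0625, the smallest possible for 5 chromosomes. The median width was larger in the middle on each chromosome, for example 563 bp against 365 bp on chromosome III and 766 bp against 528 bp on chromosome V.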

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

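Among the tests in this part, those of input reads at matched width and of the 100 strongest listed regions were chosen only after the values they concern had been seen. In 5 measures compared over the 6 chromosomes, the X chromosome stood apart from the autosomes in 2, by a gap to the nearest chromosome that exceeded Dixon's 95% critical value as a share of the whole range. These were its median width of 1028 bp, with a gap of 0.675 of the range, and its median fold of 1.82, with a gap of 0.697. The rule marks about 1 in 20 groups by chance, and chromosomes are not replicate samples. The number of regions per Mb was also lowest on the X chromosome but did not stand apart by this rule, with a gap of 0.377.

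The first pattern is the low number of X regions. A loss of only weak X regions at the significance threshold would leave X its full share of the strongest regions. In the strongest 10% of the list the X share was 6.27% (exact 95% interval 4.71 to 8.17) against 17.7% of the span. If all 47 absent top ranks had been X regions, that share would have been 11.4% (9.35 to 13.7). These values argue against a loss of weak regions alone. A lower fold over all X regions would both remove regions at the threshold and lower the rank of the rest. A loss of that kind is not excluded. The X share of the weakest 10% was 7.14% (5.47 to 9.14). The argument from the strongest 10% does not reach to the very top of the list. Of the 100 strongest listed regions 11 were X regions, or 11.0% (5.62 to 18.8), and of the 25 strongest 3 were (interval 2.55 to 31.2%). Both intervals include 17.7%, so for the 100 strongest by q-value a full X share cannot be told apart from a reduced one. Ranked by the lower 95% limit of the fold, 2 of the first 100 were X regions. Whether X DNA was sampled more thinly stays open, and its effect cannot be told apart from a true lack of regions. Input reads gained per added bp of region were 1.27 times as many on the X chromosome as on the autosomes (95% bootstrap interval 1.21 to 1.33). This ratio, with its interval, lay above the bound set beforehand as speaking against thinner sampling. With 1 X chromosome the interval cannot cover the spread between chromosomes. Single autosomes ranged from 82.5 input reads per added kb on V to 104.5 on III, against 120.5 on the X chromosome. The bound cannot decide, however, because the input number is the one after the authors' scaling. That number also exists only for regions that passed the test of ChIP against input. Gene number and gene activity on the X chromosome were not analysed here, and no biological explanation was tested.

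The second pattern is the low fold of X regions. That larger regions pass the threshold at a lower fold is argued against as the whole cause, since within 10 classes of equal size by total reads the X difference in log2 fold was −0.41 (95% interval −0.44 to −0.38), against −0.44 unmatched. At matched width, X regions had more input reads, by 0.27 on the log2 scale (95% interval 0.23 to 0.31), and fewer ChIP reads (−0.13, 95% interval −0.18 to −0.09), and the 2 add up to the matched difference in fold of −0.40 by definition. The input reads made up 66.8% of the matched difference. This splits the difference without giving its cause. An input excess and a ChIP deficit as sources of the lower fold cannot be told apart, because both numbers exist only for regions that passed the test of ChIP against input and the authors' scaling of the input is not given in the sources used here.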

How the results depend on the processing

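Of 23 alternatives to 6 results, 21 kept the direction and the side of the threshold of 0.05. The exceptions, 2 in number, concerned the central against the outer parts of the chromosomes: the difference, central minus outer, was −6.38 regions per Mb and became 11.4 kb per Mb when covered length was counted (exact sign-flip permutation p = 0.031), or 13.7 kb per Mb on the autosomes alone (p = 0.0625, the smallest possible for 5 chromosomes), which follows from the larger widths in the middle. The X difference in regions per bin lay between −58.7 without chromosome I and −75.5 without chromosome V. It was −34.3 in the stronger 50% of the regions. That set holds 4061 of the 8121 regions, and fewer regions make any difference in number smaller. The excess of X width shrank from 1.28 to 0.84 (log2) when neighbours within 1000 bp were merged. The X difference in log2 fold lay between −0.51 in the stronger 50% of the regions and −0.40 at matched width. Merging regions within 100 bp removed none and says nothing about stability. The tests of the X chromosome, of its width and fold and of the spacing, with all their alternatives, and the alternatives on the autosomes alone were chosen after seeing the data. Alternatives that need gene positions were not run. No paired analysis was possible because the only list combines the replicates, and for the same reason no replicate was left out. Regions that missed the q-value limit of 0.01 are not in the list, and whether they lacked enrichment or reads is unknown. The 47 absent ranks are in none of the counts.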

Other observations

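Ranked by fold in place of q-value, the list was led by regions shorter than those leading by q-value, and 5 of the first 10 lay on chromosome II. Chromosome II held 17.9% of all listed regions. The first 10 were chosen after their values were seen, by the lower 95% limit of the fold. The 47 absent ranks and the regions without read numbers, among them the 3 strongest listed, could not enter this ranking. The first lay on chromosome II from 13823953 to 13824863, 911 bp with 914 ChIP and 37 input reads, a fold of 24.7 (95% interval 17.8 to 35.3). A region of 210 bp just before it, from 13821987 to 13822196, held 72 ChIP and 2 input reads (fold 36, interval 9.61 to 303). The second lay on chromosome V from 9088637 to 9089256, 620 bp with 479 ChIP and 21 input reads, a fold of 22.8 (14.8 to 37.2), and a neighbour from 9090911 to 9091754 had a fold of 10.6 (7.60 to 15.1). Chromosome II from 5543385 to 5544738 and from 5844637 to 5845557 had folds of 10.4 (8.45 to 12.8) and 10.6 (8.44 to 13.4). Chromosome III had 2 of the first 10, from 12249761 to 12251307 with a fold of 9.70 (7.85 to 12.1) and from 12122159 to 12123565 with a fold of 10.5 (7.40 to 15.4).

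Only 24 regions stood in both the 100 strongest by q-value and the 100 strongest by the lower limit of the fold. The median width was 4764 bp in the former and 1337 bp in the latter, against 506 bp in the whole list. X regions numbered 11 of 100 by q-value and 2 of 100 by fold. Over all regions with read numbers, the lower limit of the fold followed −log10 q (Spearman rho = 0.85). For the fold itself rho was 0.45. The fold, its limit and the q-value rest on the same read numbers, so correlation among them is built in. Which regions lead the list thus depended on the measure, although the lower limit and the q-value ranked the whole list much alike.

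Input reads per added kb of region differed among the autosomes as well, from 82.5 on chromosome V (95% bootstrap interval 79.1 to 85.5) to 104.5 on chromosome III (99.0 to 109.5), against 120.5 on the X chromosome (116.2 to 125.0). ChIP reads per added kb were 248.5 on the X chromosome (230.0 to 266.4) and 250.9 on the autosomes (244.3 to 257.4). These intervals overlap, so the ChIP deficit of X regions at matched width does not show in the slopes.

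The list held 261 regions under 20 bp, of which 31 were 1 bp wide. The 260 of them with read numbers had a median of 29 ChIP and 8 input reads. How reads were assigned to a region is not given in the sources used here.

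The third pattern is the absence of the 47 top ranks, and its test was chosen after the ranks had been seen. Numbers too small for double-precision arithmetic are a candidate cause. The smallest listed p had a log10 of −302.4, near the smallest normal double at −307.7, and the constant rank shift left no rank absent between the lines whose read numbers were recovered. The same rank shift and smallest p would arise if the top of the list had been left out for another reason. The 3 strongest listed regions had no recoverable read numbers, and the third had a q-value of few digits, 3.7144e-296. Coarse values of that kind go with a limit of precision, and an omission alone would not account for them. An omission could still have occurred as well, so the cause stays open. With the 47 absent ranks, 8168 of 18572 tested regions (44.0%) would have passed the limit.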
